A study of Homo sapiens with 90 samples.

How the data were processed

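RNA of TK6 cells, a human lymphoblastoid (B cell derived) line, was measured on 90 two-colour Agilent arrays, 2 for each of 45 compounds given for 4 h. On each array the treated RNA carried one dye and the vehicle control RNA the other, and the second array of a compound carried the dyes the other way round. Both arrays of a compound lay on the same slide, and the 13 slides held up to 8 arrays each. The labels do not say whether the arrays of a compound came from separate cultures, nor whether compounds shared a vehicle culture. The compound was therefore the replicate in each comparison of groups. The p-values of single compounds measured only the spread between dye-swapped arrays, which may be technical. That spread was pooled over all 45 compounds for each gene and includes dye effects that differ between slides. It does not show how well the 2 arrays of a given compound agreed.

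Per the file headers, the spot and background intensity values were pixel medians from Agilent Feature Extraction 10.7.3.1, for green (Cy3) and red (Cy5), with no normalization. The deposited processed intensity signals were background-subtracted, detrended and dye-normalized by that program, per the file headers. Per the file headers, the scanner's log10 ratio was the log10 of red over green processed signal, and the spot flags (well above background, saturated, non-uniform or population outlier) were 0 or 1. The deposited series value table equalled the scanner's log10 ratio to within 0.004999, with a median of 0 on each array, so its scale, centring and direction were known. Each array held 62976 spots, of which 58717 were no controls, and 42405 probes. Symbols came from the files' accessions through a RefSeq gene table of assembly GRCh38.p14, used for names only. This gave 1 symbol to 25715 probes, left 16690 without one, and paired no accession with several symbols.

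Green and red median signals were corrected with normexp (offset 50) and normalized within each array with loess (span 0.3, weight 0 for control and outlier spots). Control and outlier spots were then left out and the spots of a probe averaged. No spot was saturated. A probe was kept if it was well above background in either channel on both arrays of at least 3 compounds, which held for 34576 probes. The brightest probe stood for each symbol, giving 16713 genes, of which 3900 had more than 1 probe. Outlier spots left 4295 gene values missing in 2307 genes. For the list tests a missing array value was filled from the dye effect and the compound's other array, which gave 16533 complete genes. Ratios were turned to treated over vehicle by the dyes in the labels, on the log2 scale. The median signal per array ran from 92 to 366 in green and from 98 to 361.5 in red. Between 39.95% and 84.65% of spots were well above background in green and between 17.33% and 75.59% in red. The number of arrays and compounds limited the precision.

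Compounds were classed from textbook pharmacology, since the labels give no class. The DNA-directed class had 14 compounds, of which 9 damage DNA directly (Busulfan, Chlorambucil, EMS, ENU, MMC, Nitrogen Mustard, Bleomycin, Doxorubicin and Topotecan) and 5 are base analogues (5AzaC, 5FU, 6-TG, 6MP and AZT). The other-target class had 26 compounds, 6 of them kinase inhibitors (Dasatinib, Gefitinib, Imatinib, Sorafenib, Staurosporine and Sunitinib). The mode of action of 5 compounds is mixed or disputed (Genistein, Hydroquinone, Diethylstilbestrol, Ciprofloxacin and Norfloxacin), and these were left unclassed. Classes, tests, the rule for named genes, 20 gene lists and most alternatives were fixed before the data were examined.

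Groups of compounds were compared with limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3, with the packages data.table (version 1.17.8) and statmod (version 1.5.0), on the mean of the 2 dye-swapped arrays. Single compounds and pairs were tested in a limma fit of all 90 arrays with 1 coefficient per compound and a common dye effect, at an adjusted p under 0.05 and at least 2-fold. Lists were compared between groups with camera (preset correlation 0.01, also with an estimated correlation) and with fry. Lists in single compounds were tested with fry and counted as raised or lowered at a mean log2 ratio of at least 0.5 either way. For the p53 list the p was adjusted over the 45 compounds. For the other lists and the members named it was adjusted over all 900 tests of a list in a compound. A compound's score for a list was its mean log2 ratio over the measured members. Differences of scores were tested by 1e+05 permutations of the compounds, or by exact permutation where a group had fewer than 10. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

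The genes named were chosen by the rule. For the class comparison these were the 12 largest differences upward and the 6 largest downward past the threshold with the sign holding in at least 10 of the 14 DNA-directed compounds. For each list they were the 3 members with the largest class difference. For each compound described they were the 2 highest and 2 lowest genes past the threshold. To these came the 3 largest members of lists that passed, whether or not the members themselves were past the threshold. For pairs they were the 2 largest differences each way, and for other group comparisons the 5 largest each way. Genes named outside the rule are stated as such.

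The steps were tested on simulated data with 200 changed genes. Values took the spread of each real gene but were drawn independently between genes and without slide effects. The self-test therefore does not show how the tests, above all those of lists, behave with correlated genes or slide effects. In the class comparison 95% of genes shifted by 0.5 log2 and 100% of those shifted by 1 log2 were recovered, with 14 false calls among 209. For directly damaging agents against base analogues the shares were 47% and 93% (13 false of 153), and for kinase inhibitors 78% and 99% (10 false of 187). For 1 compound 98% were recovered at 1.5 log2 and 100% at 2 log2, with 0 false calls. Data with no changed gene gave 0 calls in each group comparison and 1 call over 44 compounds. Both camera and fry called the 1 list shifted by 0.3 log2 and 0 of the others.

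Alternatives covered background correction, processed signals, median centring, the series value table, probe filters, probe averaging, dye orientation, dye effects, slide as a block, class membership, other tests and variance models, thresholds, and left-out arrays or compounds. Added after the data were seen were a dye effect per slide, random slide blocks for the group comparisons, slide means, leaving out 3 dim slides with another dye effect, leaving out Methyl Carbamate and Esomeprazole, leaving out MMC, leaving out 3 sets of genes, and leaving out each compound in the class comparison and in the list tests within families. Probes without a symbol were left out of the gene tests and analysed apart. The panel of genes that the series title names was absent from the files at hand and was not scored.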

Results

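The transcriptional response of TK6 cells, a p53 wild-type human lymphoblastoid line, to 45 compounds was measured after 4 h as the log2 ratio of treated over vehicle RNA. The series addresses genotoxicity screening, so the central question was which genes separate compounds that act on DNA from the rest. There were 14 DNA-directed compounds, 26 with another target and 5 left unclassed, with 2 dye-swapped arrays each (90 arrays). The median green signal per array was 205.5 (range 92 to 366) and the median red signal 169.2 (98 to 361.5). The arrays of a compound correlated across genes by 0.08 to 0.87 (median 0.58) after removal of each slide's dye effect, although genes are not independent replicates. That dye effect is the mean of the slide's own few arrays, so its removal alone makes these correlations more positive. With a dye effect common to all slides 12 of the 45 correlations were negative.

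DNA-directed compounds raised a small set of genes, most of them direct targets of the tumour suppressor p53. CDKN1A, which encodes the cell cycle inhibitor p21, differed most: its mean log2 ratio was 1.22 ± 0.85 (SD, n = 14) with DNA-directed and -0.08 ± 0.67 (SD, n = 26) with other-target compounds, a difference of 1.31 (SE 0.23, adjusted p = 0.00739), positive in 13 of 14. TRIAP1, a p53-regulated inhibitor of apoptosis, was higher by 0.78 (SE 0.15, adjusted p = 0.0227). PHLDA3, a repressor of Akt, was higher by 0.64 (SE 0.14, adjusted p = 0.0456). EI24 (0.46), the cell cycle repressor E2F7 (0.44) and the ubiquitin ligase subunit FBXO22 (0.39) completed the p53 targets. GXYLT1, a glycosyltransferase, was also higher (0.34, SE 0.07, adjusted p = 0.0269).

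The mitochondrial transport adaptor TRAK1 was the 1 gene that was lower, by -0.43 (SE 0.08, adjusted p = 0.0137), with the same sign in 13 of 14 compounds. In total 8 of 16713 genes differed between the classes by limma's two-sided test, 7 higher and 1 lower, and 1722 had an unadjusted p under 0.05. With slide as a block the count was 62 (7 higher and 55 lower), which rested on 1 slide, the only one to hold both classes (5AzaC, 6-TG and MMC against Cycloheximide). Within that slide each of the 8 genes kept its direction, from a difference of 0.11 for E2F7 to 1.74 for CDKN1A, and -0.20 for TRAK1. By limma the count was 0 without 3 slides of low signal, mostly in red, that held 10 compounds (1270 at unadjusted p under 0.05). In that fit all 8 genes had the same direction and CDKN1A differed by 1.34 (adjusted p = 0.103). The compounds left out include the DNA-directed Bleomycin, Chlorambucil, Doxorubicin, 5AzaC, 6-TG and MMC. The slide with both classes was 1 of the 3, so no slide left held both. Leaving out 1 compound at a time gave from 3 genes, without Topotecan, to 42, without 5AzaC.

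The p53 target list as a whole was shifted. Of its 36 measured members 35 were higher with DNA-directed compounds, 24 of them past the threshold adjusted over the list alone and 6 over all genes. BTG2, an antiproliferative gene, was positive in all 14 compounds (mean 1.02 ± 0.83, SD) and differed by 0.83 (SE 0.19, adjusted p = 0.0667 over all genes). The mean p53 target score was 0.42 ± 0.38 (SD, n = 14) against 0.04 ± 0.18 (SD, n = 26), a difference of 0.38 (two-sided permutation p = 0.00014). With slide as a block the difference was 0.20 (permutation p = 0.75, where the 4 possible arrangements allow no p under 0.25). That value is also the one within the shared slide, where the means were 0.14 and -0.06.

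**Figure D1:**
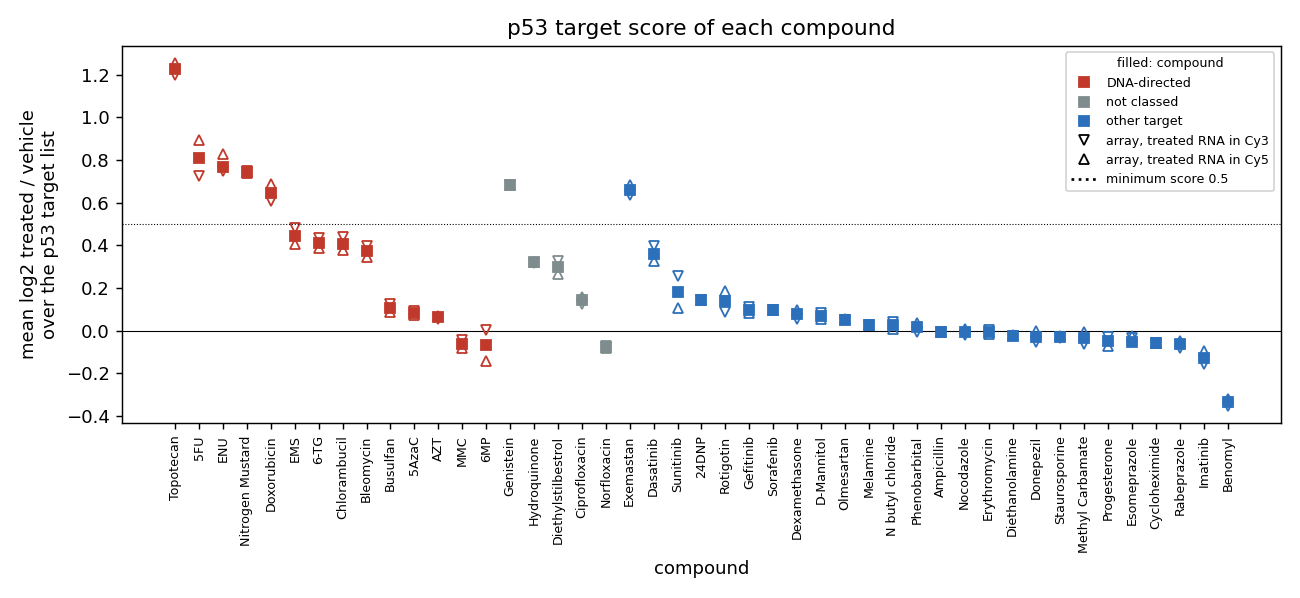
Mean log2 ratio of treated over vehicle over the p53 target list for each compound, grouped by class; squares are compounds and triangles their 2 arrays. The dotted line marks a mean of 0.5, which 7 compounds exceeded, from Doxorubicin at 0.65 to Topotecan at 1.23.

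The list was raised, by fry and with a mean log2 ratio of at least 0.5, in 7 of 45 compounds. They were Topotecan (400 nM, mean 1.23), 5FU (400 µM, 0.81), ENU (500 µM, 0.77), Nitrogen Mustard (200 nM, 0.74), Genistein (20 µM, 0.68), Exemastan (100 µM, 0.66) and Doxorubicin (1.2 µM, 0.65). Topotecan, a topoisomerase I poison, raised 20 list members at least 2-fold, led by SESN2 (2.57), BTG2 (2.45) and GADD45A (2.25). In 5FU the leading members were CDKN1A (2.80), SESN2 (1.78) and the receptor gene EDA2R (1.68). ENU raised SESN2 (1.85), PRKAB1 (1.53) and TRIAP1 (1.53), and Nitrogen Mustard BTG2 (2.31), CDKN1A (2.08) and GADD45A (1.81).

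Doxorubicin raised BTG2 (1.84), SESN2 (1.56) and TP53I3 (1.35). The other-target compound on the list was Exemastan, a steroid, with CDKN1A at 2.50, SESN2 at 1.68 and BTG2 at 1.40, and the unclassed one was Genistein, with CDKN1A at 1.77, SESN2 at 1.38 and BTG2 at 1.22. Raised lists were found in 5 of 14 DNA-directed and 1 of 26 other-target compounds (Fisher's exact test, two-sided p = 0.0143, odds ratio 12.9, 95% interval 1.22 to 679). By fry alone 22 compounds passed, 11 DNA-directed, 7 other-target and 4 unclassed (Fisher's exact p = 0.0027). With the minimum applied 12 compounds passed on processed signals or on the values of the series table, 9 of them DNA-directed. Single genes were less uniform: CDKN1A was past the threshold and higher in 10 DNA-directed compounds and in Exemastan, Diethylstilbestrol, Genistein and Hydroquinone, and it was lower in Imatinib (-1.27). It stood at 1.03 in MMC, whose list mean was -0.06.

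Beyond p53, lists of cell cycle genes were shifted between the classes by camera, but none of them kept the call with an estimated correlation (adjusted p = 0.285 for each). For the replication-dependent histone genes, which package newly made DNA, 42 of 43 members had a negative difference and 36 passed adjusted over the list alone, though 0 over all genes by limma. Over the compounds the histone score followed that of small and ribosomal RNAs, which also lack a poly(A) tail (Pearson r = 0.549, permutation p = 7e-05, adjusted p = 0.00014 over 2 relations, and Spearman 0.506, p = 0.00037). The r was 0.509 without Methyl Carbamate and Cycloheximide and 0.592 within slides. The histone score was -0.62 ± 0.59 (SD, n = 14) with DNA-directed against -0.04 ± 0.80 (SD, n = 26) with other-target compounds, led by H3C10 (difference -0.85), H2BC11 (-0.72) and H2BC10 (-0.72). Mitosis genes were lower in 22 of 24 members, 12 of them past the threshold adjusted over the list alone, with the largest differences in CENPF (-0.52), CENPE (-0.48) and the spindle checkpoint kinase gene BUB1B (-0.46). G1/S and replication genes were higher in 23 of 24 members, of which 2 passed adjusted over the list alone, and the largest were the replication clamp gene PCNA (0.44), CCNE2 (0.42) and UNG (0.23).

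By camera random splits of the compounds into groups of these sizes gave a median of 6 lists. The real classes gave 8 of the 20, of which only the p53 list kept the call with an estimated correlation. Those that were higher were p53 targets (adjusted p = 1.4e-30), G1/S and replication genes (1.6e-07), the heat shock response (0.00641) and immediate early genes (0.0416). Those that were lower were the histones (1.1e-25), mitosis genes (1.1e-12), the amino acid and ATF4 response (0.00124) and metallothioneins (0.0226). With an estimated correlation the p53 list kept its call (adjusted p = 0.0191), and the others lost it: adjusted p = 0.285 for histones, mitosis and G1/S genes, and adjusted p = 0.684 for ATF4, heat shock, immediate early genes and metallothioneins. Fry gave an adjusted p of 0.00152 for the p53 list and 0.126 for histones, mitosis and G1/S genes. MMC carried the heat shock and ATF4 calls, which were lost without it (differences of 0.06 and -0.08, camera adjusted p = 0.428 and 0.121). The metallothionein score was 2.24 in Imatinib, against an other-target mean of 0.32. The immediate early score reached 0.85 in 1 topoisomerase poison or strand breaker, against a DNA-directed mean of 0.06. These 2 class calls were not tested without those compounds. With each slide's class mean as 1 value 4 lists passed (p53 targets, histones, mitosis and G1/S genes), and 5 passed without the 3 slides of low signal.

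In the heat shock list HSPA8 (0.61), HSPA1B (0.47) and DNAJA1 (0.33) had the largest differences, and in the ATF4 list PPP1R15A (-0.53), CTH (-0.47) and SLC7A11 (-0.42), none past the threshold. Among immediate early genes BTG2 (0.83), IER3 (0.51) and MYC (-0.40) led, with 2 members higher adjusted over the list alone, and among metallothioneins MT2A (-0.35), MT1X (-0.31) and MT1L (-0.29). With slide as a block 8 lists passed, but immediate early genes turned lower (adjusted p = 3.6e-05), and mitosis genes (0.204), G1/S genes (0.204), ATF4 (0.720) and metallothioneins (0.830, turned higher) were no longer called. The p53 list (0.0344), histones (3.6e-42) and heat shock (6.7e-05) kept their direction. Within the shared slide the list differences were -2.32 for histones, -0.15 for mitosis genes, 0.14 for G1/S genes, 0.88 for heat shock, -0.65 for immediate early genes, -0.19 for ATF4 and 0.04 for metallothioneins.

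**Figure D2:**
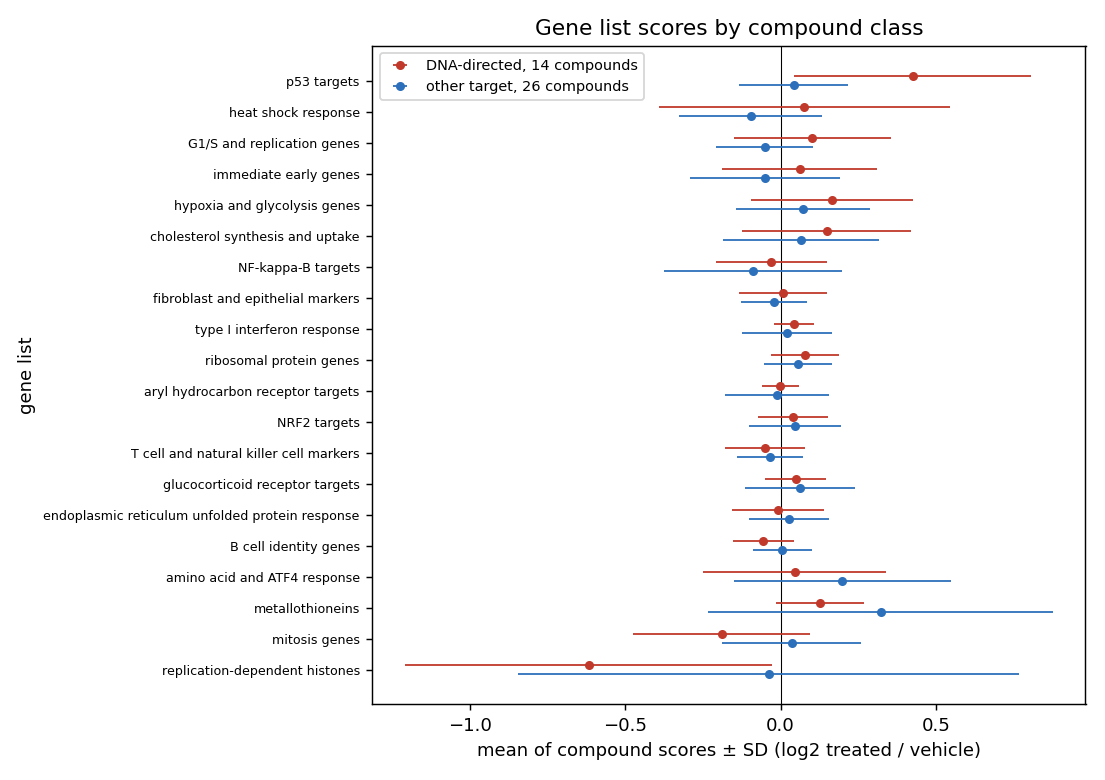
Mean score ± SD (log2 treated over vehicle) of 20 gene lists for 14 DNA-directed and 26 other-target compounds. The p53 list lies at 0.42 against 0.04 and the histone list at -0.62 against -0.04.

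The remaining 12 lists did not pass between the classes by camera. With slide as a block, which rested on the shared slide, 4 of them did: NF-kappa-B targets (adjusted p = 3.4e-06) and B cell identity genes (0.0344) lower, NRF2 targets (0.00469) and ribosomal protein genes (0.0233) higher. For NF-kappa-B targets this was opposite to the direction over all slides. The other-target side of the shared slide was Cycloheximide alone, so the 4 calls cannot be told from an effect of that compound. With each slide's class mean as 1 value none of the 4 passed by camera (adjusted p = 0.937, 0.276, 0.826 and 0.385 in the same order). Cholesterol synthesis and uptake genes had an adjusted p of 0.0615, led by IDI1 (0.35), INSIG1 (0.29) and FDPS (0.23), and hypoxia and glycolysis genes 0.103, led by ALDOC (0.41), LDHA (0.36) and BNIP3L (0.35). B cell identity genes (adjusted p = 0.474) included EBF1, a transcription factor of early B cells, at -0.87 (SE 0.20, adjusted p = 0.0667), lower adjusted over the list alone, with PAX5 (-0.30) and CIITA (-0.19). NF-kappa-B targets (0.760) held CCL3 (0.78), TNF (0.48) and CCL4 (0.31), with 2 members higher adjusted over the list alone. The unfolded protein response had an adjusted p of 0.529 (HERPUD1 -0.37, DNAJB9 -0.19, XBP1 -0.18), NRF2 targets 0.940 (SLC7A11 -0.42, GCLC -0.19, PGD 0.18) and glucocorticoid receptor targets 0.760 (PER1 -0.39, TSC22D3 -0.32, SGK1 0.23). Aryl hydrocarbon receptor targets (0.760; ALDH3A1 0.20, CYP1B1 -0.09, TIPARP -0.08), the type I interferon response (0.736; IRF7 0.17, IFIT3 0.12, OAS2 0.11) and ribosomal protein genes (0.474; RPS3 0.14, RPL5 0.11, RPL7 0.11) moved little. Markers of cells the culture should lack differed little between the classes. The camera adjusted p was 0.654 for T and natural killer cells (TRAT1 -0.12, NKG7 0.10, CD2 -0.07). It was 0.736 for fibroblasts and epithelia (KRT18 0.07, DCN 0.04, COL1A1 0.03), of which 5 of 12 were measured. These are differences of ratios and do not show that the markers were absent. NKG7 was above background in both channels on 90 arrays and TRAT1 on 2.

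More genes passed when the directly damaging agents alone were set against the other-target compounds. Without the 5 base analogues 213 genes differed, 155 higher and 58 lower, and 17 of the higher ones were p53 targets. This count was not compared with random splits, so the number that chance would give is not known. Of the directly damaging agents only MMC shared a slide with an other-target compound, Cycloheximide, so slide and class could hardly be told apart here. Named after their values were seen, the largest were CDKN1A (1.45), BTG2 (1.05), TRIAP1 (1.02), SERTAD1 (0.99), the epithelial transcription factor gene ELF3 (0.90), PLK3 (0.86) and the antiproliferative gene TOB1 (0.80, SE 0.12, adjusted p = 0.000167), each positive in 9 of 9. The lowest were EBF1 (-1.04, 7 of 9 negative), the p53 relative TP63 (-0.83, 9 of 9) and FAM72A (-0.76, 7 of 9).

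Set against the base analogues themselves, directly damaging agents had higher G1/S and replication genes by camera, a call lost with an estimated correlation (adjusted p = 0.654). Of the members 23 of 24 were positive and 10 passed adjusted over the list alone, with scores of 0.21 ± 0.26 (SD, n = 9) and -0.09 ± 0.05 (SD, n = 5). MMC, at 0.86, was far above the other 8, and without it their score was 0.13 ± 0.09 (SD, n = 8, camera adjusted p = 3.1e-06). Histones were lower by camera, at -0.80 ± 0.58 (SD, n = 9) against -0.29 ± 0.49 (SD, n = 5), but not with an estimated correlation (adjusted p = 0.658). By camera 6 lists passed: G1/S genes (adjusted p = 1.6e-07), heat shock (0.00121), ribosomal proteins (0.00121), p53 targets (0.00121) and the unfolded protein response (0.0360) higher, and histones lower (2.6e-10). None kept the call with an estimated correlation (adjusted p = 0.654 for G1/S genes, 0.713 for p53 targets and 0.658 for the other 4). The heat shock difference of 0.39 fell to 0.23 without MMC (adjusted p = 0.00410), and the unfolded protein response lost its call in 6 of 14 fits without 1 compound. No single gene passed limma's test (0 of 16713, with 2439 at unadjusted p under 0.05 and a smallest adjusted p of 0.106), and Agilent's processed signals gave 1.

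The p53 score was 0.52 ± 0.38 (SD, n = 9) against 0.26 ± 0.36 (SD, n = 5), a difference of 0.26 that was within the spread (exact permutation, two-sided p = 0.247). Among the analogues 5FU reached 0.81 and 6-TG 0.41, while 5AzaC (0.08), AZT (0.06) and 6MP (-0.07) lay near 0. Only 1 slide held both families, MMC against 5AzaC and 6-TG, and with slide as a block the difference was -0.31 (exact permutation p = 0.667 over 3 arrangements, which allow no p under 0.05). On that slide G1/S genes differed by 0.91 and histones by -0.36, and 1147 genes passed in the blocked fit, which rests on MMC alone.

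Kinase inhibitors differed from the 20 remaining other-target compounds in 4 genes, none of which passed with slide as a block. Imatinib, Sorafenib and Sunitinib shared 1 slide that held none of those 20 compounds. The blocked fit therefore rested on Dasatinib, Gefitinib and Staurosporine. NEK2, a centrosomal kinase, was higher by 0.46 (0.47 ± 0.11, SD, n = 6, against 0.01 ± 0.16, SD, n = 20; SE 0.07, adjusted p = 0.00819). BRD8, a chromatin reader, was higher by 0.61 (SE 0.10, adjusted p = 0.00819) and TSC22D2 by 0.52 (SE 0.10, adjusted p = 0.0375). LTA, which encodes lymphotoxin alpha, was lower (-0.68, SE 0.11, adjusted p = 0.00819), and all 4 genes had the same sign in 6 of 6 inhibitors. These 4 were all that passed limma's two-sided test of 16713 genes, with 1744 at unadjusted p under 0.05.

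The mitosis list was higher in 23 of 24 members, 16 of them past the threshold adjusted over the list alone (camera adjusted p = 1.2e-13, but adjusted p = 0.232 with an estimated correlation). Metallothioneins, which bind zinc and copper, were higher too (7 of 10 adjusted over the list alone, camera adjusted p = 0.000112, adjusted p = 0.363 with an estimated correlation). This call rested on Imatinib (2.24), without which the difference in score fell from 0.58 to 0.29 (adjusted p = 0.0540). Ribosomal protein genes were higher (camera adjusted p = 0.00229, adjusted p = 0.771 with an estimated correlation) and T and natural killer cell markers lower (0.0366, adjusted p = 0.232 with an estimated correlation), and both lost the call without Imatinib (adjusted p = 0.123 and 0.0540), the markers also without any 1 of 4 other compounds. With slide as a block 0 genes passed (742 at unadjusted p under 0.05). Within the 3 slides that held both kinds the differences were 0.30, 0.60 and 0.52 for NEK2, 0.70, 1.03 and 0.39 for BRD8, 0.75, 0.13 and 0.63 for TSC22D2, -0.67, -0.90 and -0.11 for LTA, and 0.06, 0.38 and 0.62 for the mitosis score. Without Gefitinib 1 gene passed, without Dasatinib 8 and without Staurosporine 13.

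The size of the response differed widely between compounds and little between classes. The median was 46 genes past the threshold, with 53 in DNA-directed, 38.5 in other-target and 65 in unclassed compounds. Imatinib (400 µM) changed 963 genes (325 higher and 638 lower), MMC (10 µM) 673, Topotecan 333, ENU 310, Esomeprazole (200 µM) 308, Methyl Carbamate (1 mM) 305 and Bleomycin (10 µM) 258. Of the 305 genes in Methyl Carbamate 300 were lower. By contrast 10 compounds changed 5 or fewer, and 5AzaC, AZT and Ampicillin changed 0 by limma. The self-test, which had no slide effects or correlated genes, recovered 98% of shifts of 1.5 log2. Part of these counts came from histone genes, small RNAs and a set of 98 genes that moved with TAFA4, without which the median was 27. The median was 128 with processed signals and 6 with median centring.

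**Figure D3:**
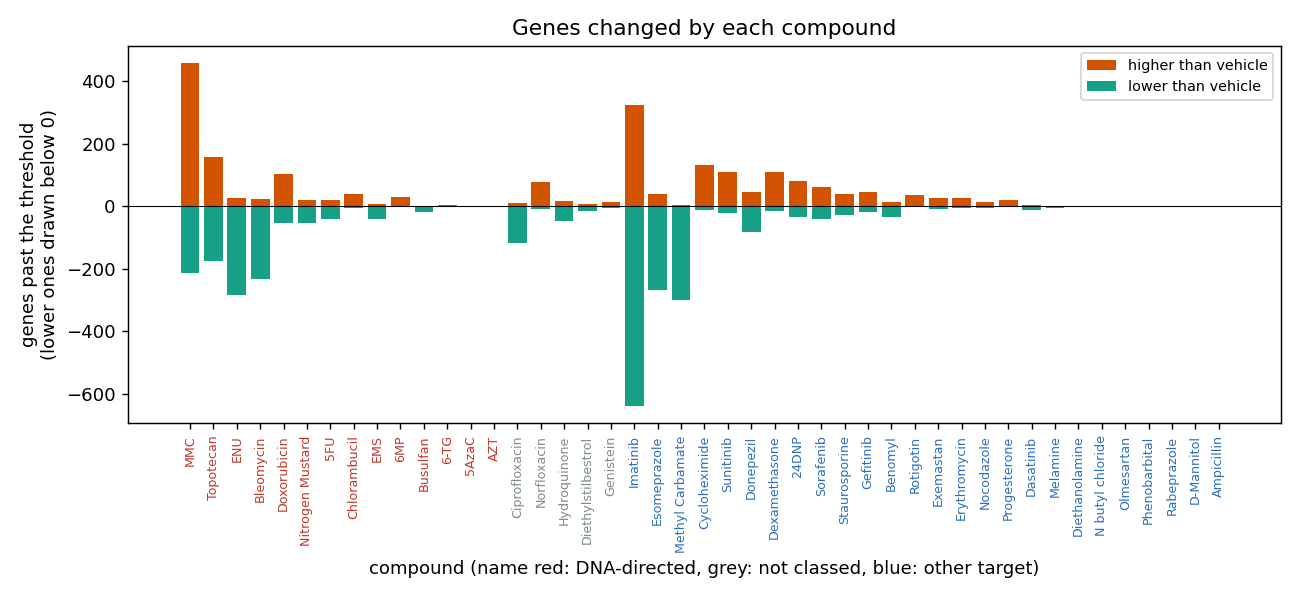
Number of genes past the threshold (adjusted p under 0.05 and at least 2-fold) for each compound, higher genes above 0 and lower genes below 0, grouped by class. Imatinib has 325 higher and 638 lower genes, and 3 compounds have 0.

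MMC, a crosslinking agent, gave a response of its own. The chaperone gene HSPA8 rose by 4.84 (SE 0.14), the tubulin gene TUBB by 3.86 (SE 0.12), HSPA1B by 2.77 and DNAJA1 by 2.29, with the heat shock list at 1.52. Replication genes rose with them, among them MCM4 (2.21), SLBP (1.82) and MCM7 (1.63), with 9 members of the G1/S list past the threshold. Genes of the ATF4 response fell, including PPP1R15A (-1.82), SLC3A2 (-1.58) and the asparagine synthetase gene ASNS (-1.48), and ASTL (-3.23) and CENPF (-2.59) were lowest. Mitosis genes fell in Topotecan (CENPE -1.33, BUB1B -1.24, BUB1 -1.22), Nitrogen Mustard (AURKA -1.41, CENPA -1.23, PLK1 -1.03) and Doxorubicin (KIF20A -1.24, PLK1 -1.03, CENPE -1.02). They rose in Staurosporine (KIF20A 1.22, AURKA 0.99, CENPA 0.82) and Dasatinib (KIF20A 0.90, PLK1 0.81, CCNB2 0.74).

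Topotecan also raised immediate early genes (EGR1 2.21, KLF10 2.07) and the transcriptional coregulator gene SERTAD1 (3.05), and lowered EBF1 (-2.26) and CBLB (-2.05). Bleomycin raised cholesterol synthesis genes (HMGCS1 2.03, INSIG1 1.44, IDI1 1.40), as did Exemastan (HMGCS1 1.68, INSIG1 1.32, MSMO1 1.09). Exemastan raised NRF2 targets as well (HMOX1 2.11, SLC7A11 1.02, TXNRD1 0.93) and lowered TXNIP (-1.92). Hypoxia and glycolysis genes rose in Ciprofloxacin (BNIP3L 1.88, BNIP3 1.65, ALDOC 1.27) and 6MP (BNIP3L 1.98, ALDOC 1.44, BNIP3 1.17).

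Several compounds without a DNA target raised the amino acid and ATF4 response, which serves stressed or starved cells: Sorafenib (mean 0.82; CHAC1 2.66, CTH 2.26, DDIT3 2.06), 24DNP (0.79; CTH 2.35, CHAC1 1.96, PPP1R15A 1.87), Dexamethasone (0.73; CHAC1 2.17, CTH 2.16, PPP1R15A 1.47), Erythromycin (0.69; DDIT3 2.36, PPP1R15A 2.30, CTH 1.44) and Exemastan (0.53; CHAC1 2.65, CTH 1.33, DDIT3 1.33). Staurosporine lowered it (-0.78; CHAC1 -2.41, CTH -1.79, DDIT3 -1.47). The list rose in 5 compounds, all other-target, and fell in 2, Staurosporine and MMC. The metallothionein list, which also holds the transporter gene SLC30A1, rose in 6 compounds, all other-target. Among them were Imatinib (mean 2.24, MT1X 3.97, MT1E 3.58, MT2A 3.49) and Gefitinib (1.31, MT1X 2.22, MT1H 1.99, MT1E 1.90). It also rose in Esomeprazole (1.26, MT1H 1.93, MT1L 1.92, MT1X 1.91), Donepezil (1.01, MT1X 1.61, MT2A 1.58, MT1H 1.57) and Dexamethasone (0.65, MT2A 1.08, MT1E 1.01, MT1X 1.01). The last was Sorafenib (0.56), where SLC30A1 (1.26) led and no metallothionein gene rose 2-fold (MT1X 0.91, MT2A 0.80).

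Glucocorticoid receptor targets rose in Dexamethasone (TSC22D3 3.52, PER1 2.47, FKBP5 0.97). In 24DNP the list rose mostly through TSC22D3 (3.05) and PER1 (1.41), since the next member, SGK1 (0.44), was under 2-fold. Dexamethasone also raised the chemokine receptor gene CXCR4 (2.67) and lowered TNF (-2.39) and ID3 (-2.05). NF-kappa-B targets fell in Benomyl (NFKBIA -2.32, CCR7 -1.83, CD83 -1.43) and Donepezil (CCL3 -2.57, TNF -2.17, BIRC3 -1.92), and rose in Cycloheximide (ICAM1 2.12, NFKBIE 1.76, NFKBIA 1.07), which stops protein synthesis. Cycloheximide also raised immediate early genes (KLF10 2.37, EGR1 1.85, JUNB 1.16) and lowered HSPA8 (-3.0) and HSPA1B (-1.73). Interferon response genes rose in Rotigotin (IFIT2 3.54, IFIT1 1.75, IFIT3 0.99), and the heat shock list fell in Erythromycin (HSPA1B -1.71, DNAJB1 -1.20, CHORDC1 -0.76). The aryl hydrocarbon receptor list fell in Imatinib mostly through ALDH3A1 (-2.64), while CYP1B1 (-0.70) and NQO1 (-0.44) were under 2-fold.

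Histone genes fell in 14 compounds, 8 of them DNA-directed, and rose in 5. The lowest means were those of Methyl Carbamate (-2.40; H3C2 -4.05, H3C10 -3.34, H4C5 -3.30), ENU (-2.02; H1-5 -2.63, H1-4 -2.58, H3C10 -2.55) and Esomeprazole (-1.59; H2BC7 -2.06, H2AC8 -2.05, H4C4 -2.02). The highest were Cycloheximide (1.91; H2AC4 2.95, H2AC17 2.47, H2AC16 2.38) and Norfloxacin (1.62; H2AC17 2.18, H2AC4 2.08, H2BC8 2.08). In Rotigotin (mean 1.00) the arrays gave 0.15 and 1.85. Small and ribosomal RNA probes moved with the histones in several of these compounds, reaching -1.22 in Methyl Carbamate, -0.68 in ENU and -1.19 in Esomeprazole. No compound moved the lists of the unfolded protein response, B cell identity, T and natural killer cells, fibroblasts and epithelia, or ribosomal proteins past both thresholds.

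**Figure D4:**
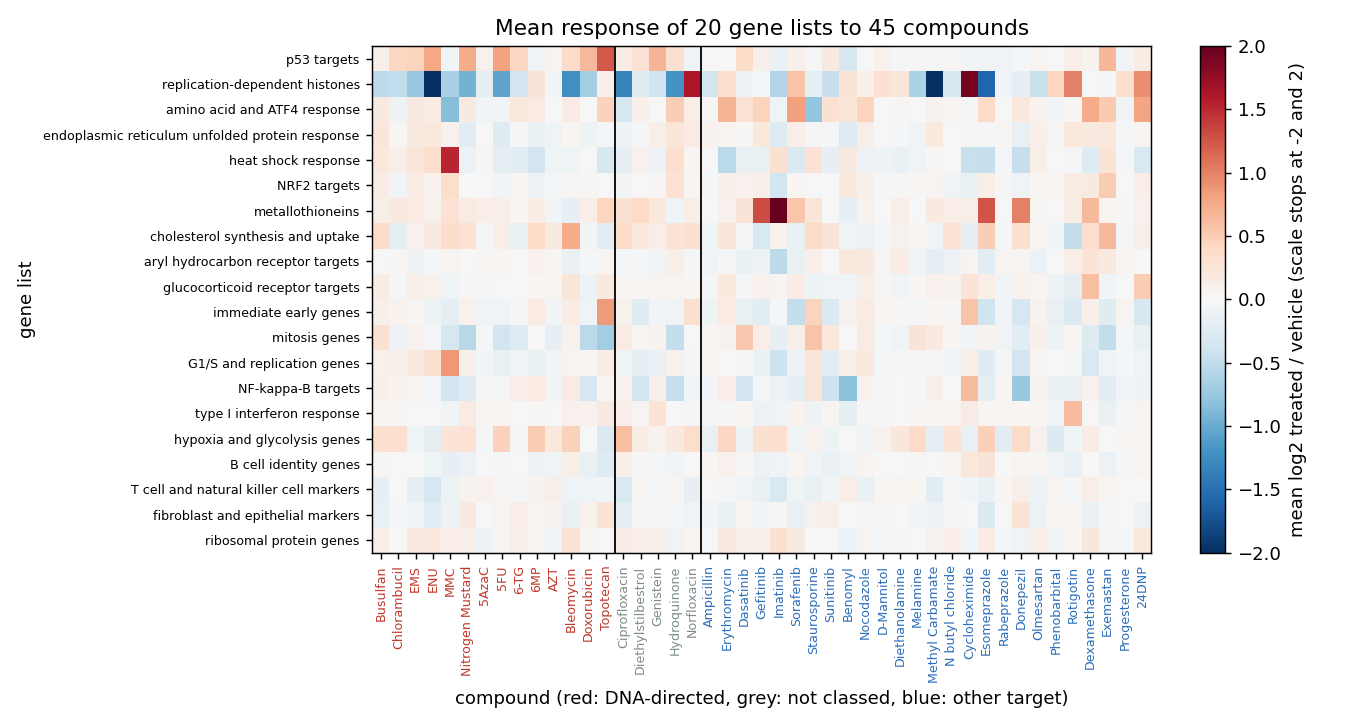
Mean log2 ratio of treated over vehicle of 20 gene lists (vertical axis) in 45 compounds (horizontal axis, grouped by class), with colours limited at -2 and 2. Histones run from -2.40 in Methyl Carbamate to 1.91 in Cycloheximide, metallothioneins reach 2.24 in Imatinib and the heat shock list 1.52 in MMC.

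Related compounds often gave different responses at the doses used, with a median of 112 genes differing within the 6 pairs. The steroids Dexamethasone and Progesterone, both at 1 mM, differed in 124 genes. TSC22D3 was higher with Dexamethasone by 3.21 (95% interval 2.82 to 3.60) and CYTIP by 2.63 (2.23 to 3.03), and TNF was lower by -2.28 (-2.67 to -1.89) and ID3 by -2.02 (-2.36 to -1.68). They shared 12 genes, all higher with both, and all 12 belonged to the 98 genes that moved with TAFA4 in several unrelated compounds. CDKN1A, given for each pair because of its class difference, was -0.60 and 0.04.

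The fluoroquinolones Ciprofloxacin (100 µM) and Norfloxacin (1 mM) moved histone genes in opposite directions. H2BC7 was at -2.10 and 2.02 (difference -4.12, 95% interval -4.81 to -3.42) and H3C12 at -1.96 and 2.15 (difference -4.11, -4.85 to -3.36), while HPS6 (1.28, 0.91 to 1.65) and ALAS1 (1.36, 0.85 to 1.87) were higher with Ciprofloxacin. The pair differed in 100 genes, and 47 genes were past the threshold in both with opposite signs. CDKN1A was at 0.55 and -0.22 (difference 0.77, 0.46 to 1.08).

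The thiopurines 6MP (1 mM) and 6-TG (4 µM) differed in 44 genes and shared 0. CDKN1A rose with 6-TG (1.56) and was at -0.12 with 6MP (difference -1.67, 95% interval -1.98 to -1.37). CCL2 was lower with 6MP (-1.83, -2.23 to -1.44), and TRAM1L1 (2.71, 2.19 to 3.23) and TAFA4 (2.49, 1.62 to 3.35) were higher. Chlorambucil (4 µM) and Nitrogen Mustard (200 nM), both bifunctional alkylators, differed in 98 genes. Each raised CDKN1A (1.5 and 2.08, difference -0.58, -0.89 to -0.28), whereas SERTAD1 rose with Nitrogen Mustard (2.06 against 0.39, difference -1.67, -2.16 to -1.18). SNORD3B-1 was lower with Chlorambucil (-1.57, -2.21 to -0.93), and TAFA4 (3.51, 2.64 to 4.37) and SULT6B1 (3.08, 2.29 to 3.86) were higher. In Chlorambucil the vehicle signal of TAFA4 was above background on only 1 of the 2 arrays. Since TAFA4 moved in several unrelated compounds, its differences here and between the proton pump inhibitors may not be effects of the compounds. Extra RNA or DNA in single samples stays open as their source.

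The proton pump inhibitors Esomeprazole (200 µM) and Rabeprazole (0.8 µM) differed in 262 genes, with BNIP3L (2.05, 95% interval 1.62 to 2.48) and MT1H (2.01, 1.59 to 2.42) higher and TAFA4 (-4.04, -4.91 to -3.18) and CASC8 (-3.34, -4.71 to -1.98) lower in Esomeprazole. The CASC8 difference rested on 1 array, since the arrays of Rabeprazole gave 0.34 and 6.86. CDKN1A did not differ detectably (-0.10, -0.41 to 0.20). The microtubule agents Benomyl (1 mM) and Nocodazole (30 µM) differed in 123 genes. NFKBIA was at -2.32 with Benomyl and 0.47 with Nocodazole (difference -2.78, -3.07 to -2.50) and CD83 at -1.43 and 0.95 (difference -2.38, -2.81 to -1.95). HMOX1 was higher with Benomyl (2.11, 1.54 to 2.68), as was SLC35B3 (1.82, 1.01 to 2.64), for which the arrays of Nocodazole gave -0.07 and -3.37, so that the difference rested on 1 array. CDKN1A was not shown to differ (-0.45, -0.76 to -0.15, adjusted p = 0.105). No pair lay on 1 slide, so slide and compound could not be told apart within a pair. The median was 5.5 with median centring, 73 with no dye effect and 226 with no fold minimum.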

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

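All tests of an explanation in this part, for the histone genes and for the p53 difference, were chosen after the result was seen, and what the test on the G1/S boundary would show was restated after its value was known.

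The p53 target score differed between the classes by 0.38, the difference that called for a closer look. An effect of the 3 slides of low signal as the cause was excluded, since without them the difference was 0.48 (permutation p = 0.00047). An offset shared by all compounds of a slide stays open as the cause, because only 1 slide held both classes: within slides the SD between compounds was 0.346 on the 5 slides with DNA-directed compounds and 0.172 on the 8 others, a ratio of 2.01 (exact permutation over slides, p = 0.0777). This ratio replaced a test on the lowest score of each of these slides (median 0.104), since the lowest of several values lies below their mean by chance.

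Histone genes ran far below the other alkylating or crosslinking agents in ENU, at -2.02 against -0.95 to -0.49. Over the 45 compounds the histone score rose and fell with that of small and ribosomal RNAs, which also lack a poly(A) tail (Pearson r = 0.549, 95% interval 0.304 to 0.726, permutation p = 7e-05, adjusted p = 0.00014 over 2 relations; Spearman 0.506, p = 0.00037; r = 0.509 without Methyl Carbamate and Cycloheximide, and 0.592 within slides). Recovery of such RNA that differed between treated and vehicle samples may therefore explain part of the histone changes, although Cycloheximide (1.91 against -0.20), Norfloxacin (1.62 against -0.23) and 5FU (-1.06 against -0.09) moved histones with little change in small RNAs. A changed share of cells at the G1/S boundary stays open, since cells held before S phase would raise G1/S genes and lower histones while cells entering S phase would raise both, and the interval of the correlation does not exclude the former (Pearson r = -0.0997, 95% interval -0.382 to 0.200, permutation p = 0.499, adjusted p = 0.499; Spearman -0.120, p = 0.434; r = -0.156 without the same compounds, and -0.108 within slides). A direct effect of the compounds on histone mRNA remains open and was not tested.

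Other compounds lay far from the rest of their family. Such results came from 7 of 42 tests of a family and a measure, and chance alone would give them in about 1 of 20 tests. MMC had the lowest ATF4 score among the alkylating or crosslinking agents (-0.85, the others -0.10 to 0.18) and the highest heat shock score (1.52, the others -0.11 to 0.35). Imatinib changed 963 genes, the other kinase inhibitors 16 to 131. Methyl Carbamate changed 305 genes, the other chemicals of its family 1 to 5. Hydroquinone had a mitosis score of -0.47, the other unclassed compounds 0.01 to 0.16. Donepezil had a metallothionein score of 1.01, the other receptor or enzyme drugs 0.01 to 0.14.

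Probes without a gene symbol were outside the comparisons of genes. Imatinib moved 870 of them past the threshold, against a median of 24 per compound and a lowest count of 0.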

How the results depend on the processing

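The settings chosen after the data were seen were a dye effect per slide, random slide blocks, slide means, leaving out the 3 slides of low signal, Methyl Carbamate and Esomeprazole, or MMC, leaving out 3 gene sets, and leaving out each compound in the class comparison and in the list tests within families. Except where a value shows it, the cause of a change was not tested.

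The count of 8 genes between the classes was 15 with a strict probe filter, 3 with arrays of treated RNA in Cy5, 15 with those in Cy3, 62 with slide as a block, 2 by Wilcoxon tests, 3 and 4 with the unclassed compounds added to the DNA-directed or the other-target class, and 213 without base analogues. It was 0 by limma without the 3 slides of low signal (1270 at unadjusted p under 0.05) and 21 without Methyl Carbamate and Esomeprazole. Leaving out 1 compound gave 3 to 42 genes: 42 without 5AzaC, 35 without 6MP or Busulfan, 34 without Exemastan, 21 without 6-TG, 20 without AZT, 14 without MMC, 5 without Doxorubicin, 4 without 5FU, EMS, ENU or Nitrogen Mustard, and 3 without Topotecan. The values of the 8 genes themselves were followed in 13 of the alternatives (data processing, dye orientation, a random slide block, and left-out slides or compounds), not with slide as a fixed block, by other tests, with other class membership, without gene sets or in the leave-one-out fits. Of these 104 values 79 stayed past the threshold, 25 did not, and 0 changed direction.

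The p53 difference of 0.38 stayed past the threshold in 57 of 58 alternatives (0.32 to 0.42 without 1 compound) and was 0.20 with slide as a block (permutation p = 0.75). The p53 list was raised in 12 compounds with processed signals and with the series value table, 22 without a score minimum and 1 at a minimum of 1, and in 7 without any 1 array. The count of 8 lists was 1 with an estimated correlation, 4 with slide means and 5 without the 3 slides of low signal. With slide as a block it was 8 again, but 4 of the lists lost the call and immediate early genes turned lower (adjusted p = 3.6e-05). Single list shifts were followed in 12 alternatives (data processing, dye orientation, and left-out slides or compounds), which leaves out the slide block, slide means, the estimated correlation, other class membership and left-out gene sets. Of these 240 shifts 221 kept their side of the threshold, 13 were weaker and 6 stronger. Without 1 compound 175 of 188 list shifts within families kept theirs and 13 were weaker.

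The median of 46 genes per compound was 128 with processed signals, 149 with the series value table, 6 with median centring, 294 with no fold minimum, 27 without histones, small RNAs and TAFA4 genes, and 46 to 49 without 1 array. Median centring left compound medians of -0.24 to 0.14 log2. Among counts of single compounds 310 of 450 stayed within 1.5 times. Within pairs the median of 112 was 5.5 with median centring, 73 with no dye effect, 226 with no fold minimum, and 96 to 123.5 without 1 array.

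Between directly damaging agents and base analogues limma's 0 genes (2439 at unadjusted p under 0.05) became 1 with processed signals and 1147 with slide as a block, and stayed 0 without any 1 compound. The p53 difference of 0.26 reversed to -0.31 with slide as a block (exact permutation p = 0.667), where MMC alone stood against 5AzaC and 6-TG, and was 0.17 to 0.40 without 1 compound.

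The 4 genes of the kinase inhibitors were 0 with median centring (3032 at unadjusted p under 0.05), Cy5 arrays (1320), slide as a block (742) and Wilcoxon tests (1478), 1 with Cy3 arrays and with a robust variance trend, 2 without the 3 slides of low signal, 7 with a strict filter and 9 with a random slide block. Leaving out 1 compound gave 1 to 13: 1 without Gefitinib, 8 without Dasatinib and 13 without Staurosporine. The values of the 4 genes themselves were followed in 10 alternatives (data processing, dye orientation and the left-out slides), not in the slide blocks, other tests, left-out gene sets or leave-one-out fits, and 23 of these 40 stayed past the threshold. Signal over background was lower in red, where as few as 17.33% of spots were well above it, which limits the precision for dim genes.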

Other observations

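Some genes responded to many compounds. The sestrin gene SESN2, which is induced by stress, was past the threshold in 17 compounds: it rose in 7 DNA-directed, 6 other-target and 3 unclassed compounds and fell in 1. BNIP3L, a mitophagy receptor gene, rose in 15 compounds, 6 of them DNA-directed and 6 other-target. The chemokine gene CCL2 fell in 16 compounds, 5 DNA-directed, 9 other-target and 2 unclassed. CCL3, another chemokine gene, fell in 12 compounds, of which 10 were other-target and the other two unclassed, while its class difference of 0.78 did not pass (adjusted p = 0.244). DDIT3 rose in 8 other-target, 1 DNA-directed and 1 unclassed compound, and fell in 1 other-target and 1 DNA-directed one. These genes were chosen after their values were seen.

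Whole responses were most alike, across genes that are not independent replicates, between ENU and Methyl Carbamate (r = 0.731, different slides), EMS and ENU (0.686, the same slide) and EMS and Methyl Carbamate (0.650). Olmesartan at 0.16 µM, with 2 genes past the threshold, also correlated with EMS (0.493), ENU (0.466) and Methyl Carbamate (0.465). Histone and small RNA scores were below 0 in each of these compounds. Whether the likeness reflects a shared action was not tested. Sorafenib and 24DNP correlated by 0.573. Pairs of compounds on 1 slide had a median correlation of 0.072, pairs on different slides 0.033. Where both compounds were other-target these were 0.041 and 0.035. Among 13201 probes without a symbol 0 differed between the classes by limma, with 782 at unadjusted p under 0.05.

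The tests on a shared vehicle and on class in this paragraph were chosen after the result was seen. TAFA4, a secreted-protein gene, and 98 genes in all moved together by large amounts in single compounds: TAFA4 was at -5.53 in Bleomycin and -4.30 in Esomeprazole, and at 4.82 in Doxorubicin, 4.57 in Sunitinib and 3.77 in Chlorambucil. The set scored 1.71 in Doxorubicin on the slide of Bleomycin, so the compounds of that slide were not all lowered. That ratio does not show the vehicle level, but the vehicle channels do. Their mean log2 level over 84 genes of the set was 9.69 and 9.86 on the 2 arrays of Bleomycin. It was 9.01 and 8.80 in Doxorubicin, 8.62 and 8.46 in Chlorambucil, and 8.39 and 8.52 in Genistein. These values argue against 1 vehicle RNA shared by all 4 compounds of that slide. A vehicle RNA shared by only some of them stays open. Vehicle channels lay at percentile 97.7 and 100 in Bleomycin and 95.5 on both arrays of Doxorubicin. They lay at 86.4 and 84.1 in Chlorambucil and at 84.1 and 88.6 in Genistein. Extra RNA or DNA in single samples may be the source and stays open. In the vehicle samples of Bleomycin and Esomeprazole it would give very high vehicle channels without very low treated ones. Treated channels of both compounds, at percentile 18.2 to 81.8, were not very low, and the vehicle channels of Bleomycin were very high. Those of Esomeprazole, at 75 and 81.8, were not, so the test did not decide. The classes did not differ detectably (difference -0.04, permutation p = 0.834), and no biological explanation was tested further.

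Compounds were also divided at random into groups of the same sizes, 100 splits per comparison with the real one. These splits ignored slides, although only 1 slide held both classes, so they address chance among compounds and not an effect of slides. In that sense chance can be excluded for the 8 genes between the classes, where the highest of the other splits gave 1 and 1 of 100 splits, the real one, was as large. It cannot be excluded for the 8 lists by camera, where 20 splits gave as many, the real one included. The other splits gave a median of 6 lists and at most 11. With a real count of 0 genes between directly damaging agents and base analogues by limma (2439 at unadjusted p under 0.05) all 100 splits were as large by construction, so nothing was tested (the highest other gave 11). For the 4 genes of the kinase inhibitors 2 splits were as large, the real one included. The share alone would exclude chance, but the other one gave 403 genes, which points to a structure of the samples that was not tested, and with slide as a block 0 genes passed by limma (742 at unadjusted p under 0.05).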
